A study of Myzus persicae with 4 samples.

How the data were processed

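Per the labels, total RNA came from dissected heads of the aphid Myzus persicae that had been moved from cabbage to a liquid diet and had fed on it for 24 h. The diet held sucrose and 20 amino acids, with or without 100 µM nicotine. RNA was amplified through aminoallyl labelling and coupled to Alexa Fluor 555 (green) or Alexa Fluor 647 (red), per the labels' protocols. Each array was a 2-colour array that carried RNA from nicotine-fed aphids in 1 channel and RNA from control aphids in the other. The labels name 3 biological replicates and 1 technical repeat array, which was read from its title as a repeat of replicate 2. Nicotine RNA carried Alexa Fluor 555 in replicates 1 and 3 and Alexa Fluor 647 in replicate 2 and its repeat array, so the dye orientation was not balanced. A mean over the 3 replicates therefore keeps part of any dye effect unless a dye term is fitted. The labels do not say how many aphids were pooled per replicate or whether the pools came from separate cages, so p-values measure only the spread between these 3 replicates.

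The deposited scanner files hold median spot intensity and median local background intensity for each channel, on a linear scale and not normalized. They were written by Agilent Feature Extraction 10.1.1.1, per the file headers. The same deposited files hold processed intensity values, which the scanner software had background-subtracted, spatially detrended and dye-normalized, per the file headers. They also hold the scanner software's log10 ratio of red over green, per the file headers, which entered none of the tests. Other columns of the deposited files are flags per spot and channel for signal well above background, saturation and outliers, per the file headers. The authors' deposited value table holds 1 column per array, and the submitters' processing notes name limma without a version. Its background correction and normalization are not given in the sources used here. Set against the red over green log2 ratios computed from the scanner intensities, the columns of the authors' deposited table correlated at 0.9999, 0.9999, 0.9998 and 0.9998 across spots for replicates 1, 2 and 3 and the repeat array, with slopes of 1, 1.001, 0.9989 and 1.001. These deposited values were therefore read as log2 ratios of red over green whose sign had not been turned by treatment. Their medians were -0.02, -0.002, -0.003 and 0.004, so each array was centred near 0. The comparison settles the scale, the centring and the order of the channels in the table, but not which RNA carried which dye, which rests on the labels.

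Log2 ratios were computed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0. Median spot signals were used because the files analysed hold no mean signal column, a departure from the preset design. Ratios were turned by the dyes in the labels so that positive values mean more signal from nicotine-fed aphids. The repeat array was averaged with replicate 2, which left n = 3. Probes were tested if the scanner had marked them well above background in at least 1 channel in every biological replicate and had not marked them as outliers. Of 14628 probes, 3408 were left out as too dim and 14 as outliers, and 11206 probes for 7687 targets were tested. The model was a limma fit with an intercept and moderated variances, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. With 3 replicates, an exact sign-flip test of a single probe cannot give a p-value below 0.25, so no such test was used. All 4 arrays shared 1 slide and 1 scan time in the file headers, so there was no slide or scan batch to test.

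The array identifies its targets by 10489 identifiers, of which 10295 are contig numbers and 194 are other sequence or clone names. None of them (0) matched the RefSeq gene table for the assembly MPER_G0061.0, and the files do not pair them with gene names. The 26 gene lists prepared for detoxification, cholinergic transmission, cuticle, chaperones, tissue markers and other functions therefore had no members that could be tested (0 lists tested), and no gene set result is reported. The rule for naming probes took those with adjusted p under the threshold and 1 sign in all replicates. If fewer than 10 passed, it took those with the smallest p and 1 sign in all replicates, given as not past the threshold. Without gene names it was limited to 2 probes in each direction, 1 per contig. The rule's words for this case speak of the largest rise and fall, and ranking by p in place of size was a reading made after it was known that no probe passed. Groups, dye directions, the model, the wording of the naming rule, the gene lists and all but 1 of the alternative settings were fixed before the data were examined.

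The fit was tested on simulated data with the probes' real intensities and backgrounds, with 50 probes changed at each size out of 14628. The changed probes were all brighter than the median, and replicates were drawn independently without a probe-specific dye effect. The real replicates correlated negatively, so the shares called are not the power for the probes tested here. At the spread between replicates seen here, it called 2% of probes changed by 1 on the log2 scale, 64% at 2, 84% at 3 and 96% at 4, with 3 unchanged probes called. At 0.25 of that spread it called 100% at each size, with 15 unchanged probes called. Among unchanged simulated probes, 5.36% had an unadjusted p under 0.05 at the full spread. The number of arrays limits the precision of every value.

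Alternative settings covered the background correction, the scanner's processed signals, median centring in place of loess, all non-control probes, a dye term, the treatment of the repeat array, the authors' deposited table, an intensity trend with robust variances and leaving out each replicate. An alternative that averaged the probes of a contig was chosen after seeing the data. Directions were compared with 1000 shuffles of each replicate's values among probes of like mean intensity, in 20 bins, with a fixed seed. Control spots (1116 of 15744 spots per array) were left out of the tests.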

Results

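Head RNA of Myzus persicae, a sap-feeding aphid with a tobacco-adapted form, was compared between insects fed for 24 h on a diet with 100 µM nicotine and insects fed on the same diet without it. Nicotine is a tobacco alkaloid that acts on nicotinic acetylcholine receptors of the nervous system. The data were 4 arrays, made up of 3 biological replicates and a technical repeat of replicate 2, each with nicotine and control RNA in separate dyes. The share of the 14628 probes well above background was 78.1% in replicate 1, 85.9% in replicate 2, 88.1% in replicate 3 and 80.5% on the repeat array. Median spot intensity in the Alexa Fluor 555 channel was 2342, 2140.5, 925 and 694.75 in the same order, against a local background between 48 and 57. In the Alexa Fluor 647 channel it was 1617, 3266.5, 2869 and 1479.25, against a background between 72 and 76. No probe (0) was saturated on any array.

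The first comparison asked which transcripts in the head differed in level between nicotine-fed and control aphids. The probe of contig300 had the smallest p-value, with a mean log2 ratio of nicotine over control of 1.29 ± 0.11 (SD, n = 3), or 2.45-fold. A probe of contig3790 had a mean of 1.88 ± 0.73 (SD, n = 3), with control signal well above background on only 1 of 4 arrays. This value is therefore approximate and is not given as a fold. In the opposite direction, contig2799 had a mean log2 ratio of -0.80 ± 0.10 (SD, n = 3), a ratio of 0.576, and contig3929 had a mean of -0.60 ± 0.29 (SD, n = 3), a ratio of 0.660. None of these contigs passed the test after correction (limma, adjusted p = 0.9998 for each). The probes were picked for 1 sign in all replicates and a small p. Their shared signs and unadjusted intervals, given below, are therefore no test. The files do not pair these identifiers with gene names, so what the contigs encode is not stated here.

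The transcript contig300 was higher with nicotine in 3 of 3 replicates, with log2 ratios of 1.27, 1.42 and 1.19, and its 95% interval in limma ran from 0.68 to 1.91. Its single probe, M_persicae300a, was well above background in both channels on 4 of 4 arrays. The transcript contig3790 was also higher in 3 of 3 replicates, at 2.63, 1.84 and 1.17 for probe M_persicae3790b, with an interval from 0.97 to 2.79. Its other probe gave 2.64, 1.78 and 1.18. The contig3790 signal was well above background in the nicotine channel on 4 arrays but in the control channel on 1 of 4, so the size of this ratio rests on a control level near background. Its mean was 1.51 without replicate 1 and 2.51 from the scanner's processed signals, the extremes over the alternative settings.

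The transcript contig2799 was lower with nicotine in 3 of 3 replicates, at -0.69, -0.88 and -0.83 for probe M_persicae2799a, with a 95% interval from -1.41 to -0.19. The second probe of contig2799 gave -0.53, -1.17 and -0.56, a mean of -0.75. The transcript contig3929 was lower in 3 of 3 replicates, at -0.93, -0.39 and -0.48 for probe M_persicae3929b, and its interval from -1.26 to 0.06 included 0. The second probe of contig3929 had a mean of -0.57. Both contig2799 and contig3929 were well above background in both channels on 4 of 4 arrays.

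**Figure D1:**
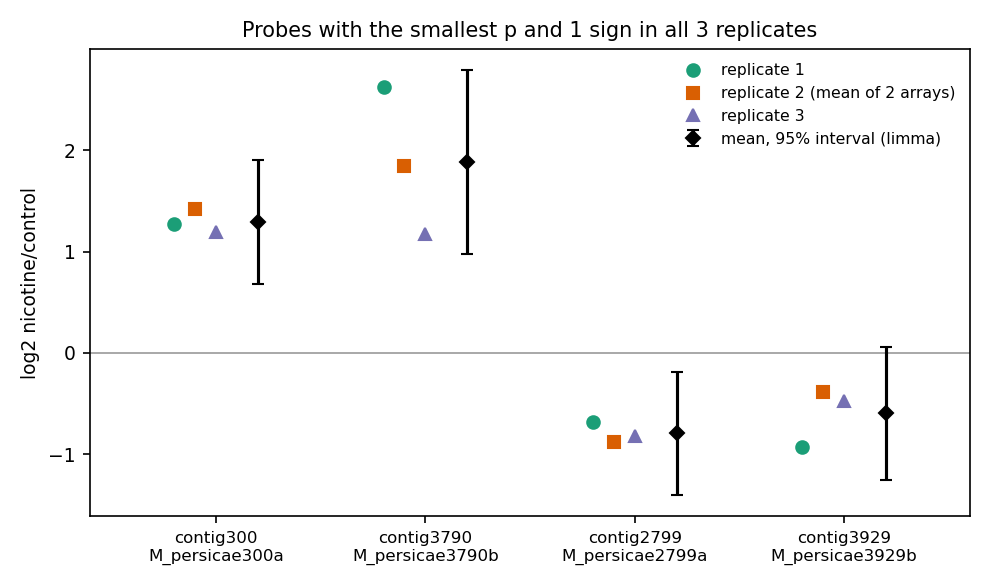
Log2 ratio of nicotine over control (vertical axis) for the 4 named probes, the 2 in each direction with the smallest p and 1 sign in all replicates, with each of the 3 replicates as a coloured symbol and the mean with its 95% limma interval in black. The rule that picked the probes required 1 sign in all replicates. The intervals are for single probes without adjustment, and only that of contig3929 included 0. No probe passed the threshold after adjustment.

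Over all contigs, 0 of 11206 tested probes passed the threshold, and the lowest adjusted p was 0.9998 (limma). Before adjustment 47 probes (0.419%) lay under 0.05, against 560.3 expected if no probe differed and replicates were independent. Of these 47 probes, 45 were higher and 2 lower with nicotine, and the 2 lower ones were the probes of contig2799. The count was 148 without replicate 1, 120 of them higher with nicotine and 28 lower, and 184 without replicate 3, with 147 higher and 37 lower. Without replicate 2 it was 190, and the balance turned to 60 higher and 130 lower. Replicates 1 and 3 then remained, both with nicotine RNA in Alexa Fluor 555, so diet and dye cannot be told apart in that fit. In each case 0 probes passed the threshold. A mean difference of at least 2-fold was found for 101 probes. The median standard error of a mean log2 ratio was 0.30, and 6788 probes (60.6%) had a 95% interval that lay inside a 2-fold difference in either direction.

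The second comparison asked whether the replicates gave the same direction of difference. Contigs differed by large amounts within single replicates. The log2 ratio was at least 2-fold from 0 for 867 tested probes (7.74%) in replicate 1, 1172 (10.5%) in replicate 2 and 2089 (18.6%) in replicate 3. These differences were reproducible within an RNA pair at 1 dye orientation, where a dye effect would be reproduced as well. For 3519 contigs with 2 tested probes, the log2 ratios of the 2 probes correlated across contigs at 0.951, 0.886 and 0.876 in replicates 1, 2 and 3 and 0.867 on the repeat array. Replicate 2 and its repeat array correlated at 0.974 across probes (Spearman 0.967), with the same sign for 93.5% of probes.

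Between biological replicates the same contigs had mostly opposite ratios. Across the 11206 probes, which are not independent of each other, the nicotine over control log2 ratios correlated at -0.23 between replicates 1 and 2 (Spearman -0.30), -0.19 between replicates 1 and 3 (Spearman -0.18) and -0.42 between replicates 2 and 3 (Spearman -0.40). The shares of probes with the same sign were 38.9%, 44.6% and 34.5%. Among the 2802 brightest probes, the Pearson correlations were -0.35, -0.11 and -0.34, with Spearman values of -0.37, 0.02 and -0.35 and the same sign for 34.5%, 53.6% and 36.4% of probes. In all, 1010 probes (9.01%) had 1 sign in all 3 replicates, where independent signs would give 25%. The median SD of a probe between replicates was 0.50, against 0.05 between the repeat arrays. The repeat arrays shared 1 dye orientation and the replicates did not, so a dye effect would enter only the first of these values. Averaging over replicates lowered the median absolute log2 ratio from 0.32 to 0.13.

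**Figure D2:**
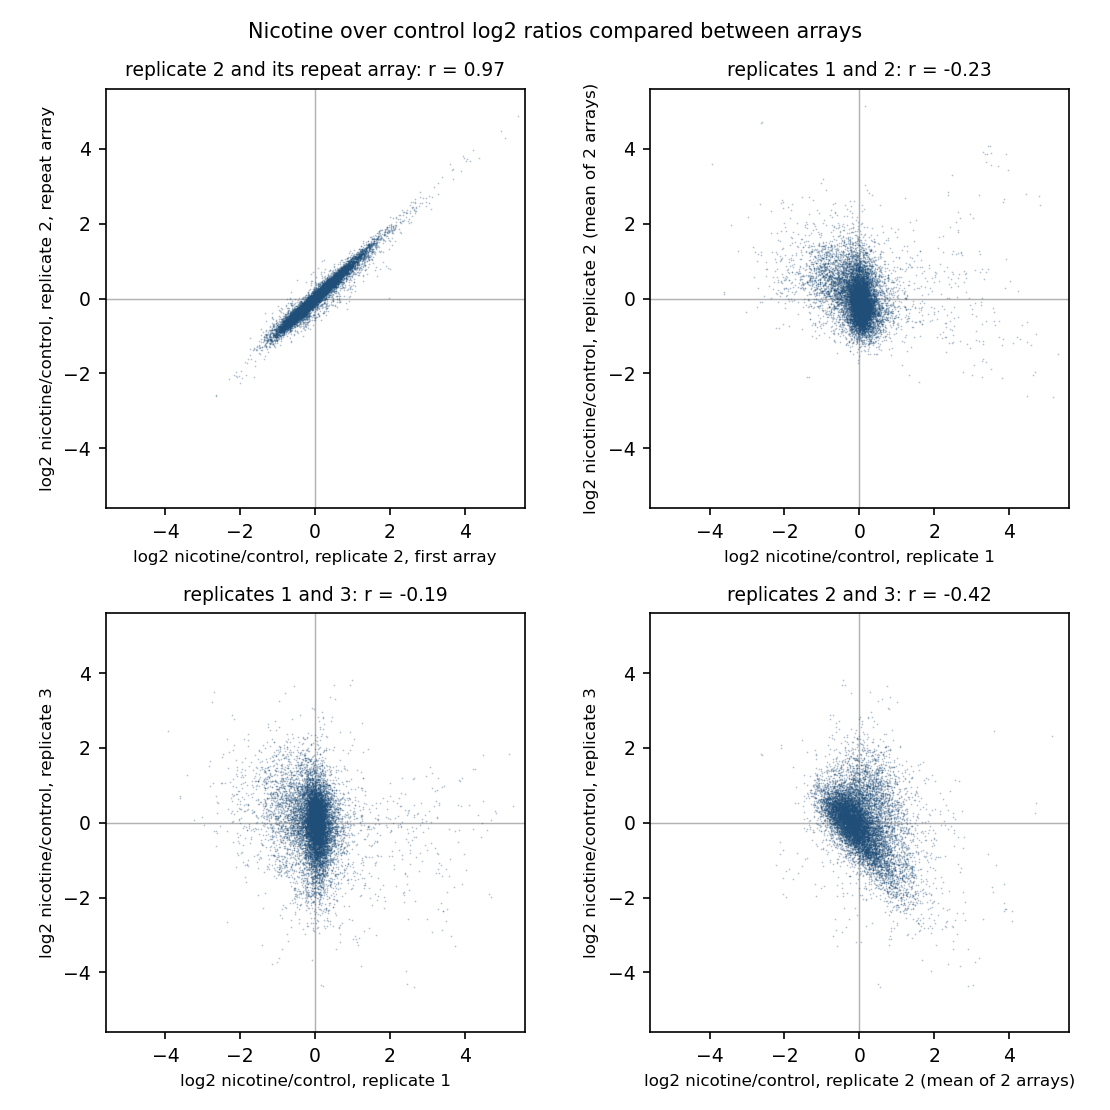
Log2 ratios of nicotine over control for each tested probe, 1 point per probe, with 1 array or replicate on each axis. The repeat arrays of replicate 2 lie along the diagonal (r = 0.97), and the pairs of biological replicates slope the other way, with r between -0.19 and -0.42.

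Replicates 1 and 3 shared a dye orientation and replicate 2 had the opposite one. Without turning signs, as red over green, the log2 ratios correlated at 0.23 between replicates 1 and 2 and 0.42 between replicates 2 and 3, but at -0.19 between replicates 1 and 3. With replicate 2 given the opposite sign, the model measured mainly a difference between dyes. Part of any diet effect stayed in this contrast, because the orientation was not balanced. In it 0 probes passed the threshold (limma, lowest adjusted p = 0.487). Before adjustment 981 probes (8.75%) lay under 0.05 in that contrast.

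A set of contigs differed by at least 2-fold between the paired RNA samples in every replicate. It held 100 probes, where shuffling each replicate's values among probes of like intensity gave a mean of 18.1 and at most 32. Shuffling moved single probes and so separated the 2 probes of a contig, which makes the shuffled range too narrow. Of the 100 probes, 30 for 24 contigs were lower with nicotine in replicates 1 and 3 and higher in replicate 2. Another 23 probes for 17 contigs were higher in replicates 1 and 2 and lower in replicate 3, and 22 probes for 19 contigs were lower in replicate 1 and higher in replicates 2 and 3. The same direction in all 3 replicates was found for 6 probes of 4 contigs, all 6 higher with nicotine, and 0 probes were lower in all 3. The shuffled counts for 1 shared direction, higher or lower, had a mean of 3.28 and ran from 0 to 12. For higher in all 3 alone, they had a mean of 1.80 and ran from 0 to 8.

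**Figure D3:**
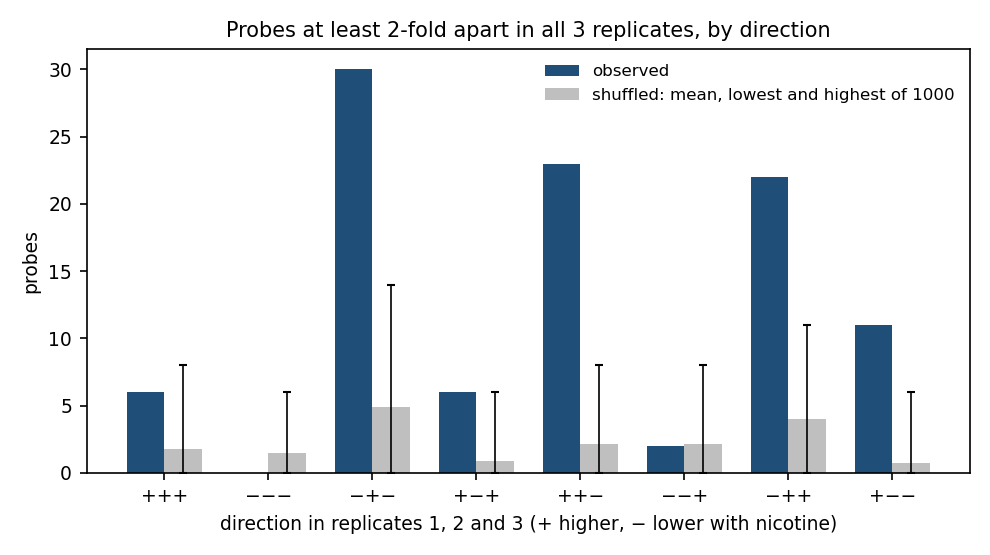
Number of probes (vertical axis) at least 2-fold apart between nicotine and control in all 3 replicates, by the sign in replicates 1, 2 and 3 (horizontal axis). Dark bars are observed counts, and grey bars with whiskers are the mean, lowest and highest of 1000 shuffles; the highest bar is the class lower in replicates 1 and 3 and higher in replicate 2, with 30 probes.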

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

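The tests of spot noise, of a wrong dye direction, of a dye effect as the whole cause and of other sign choices were chosen, with their bounds, after the replicates had been compared. The spike-in control spots, which the comparison of diets did not use, carried signal, with 200 of 200 spots well above background on every array. For 9 of the 10 spike-in sequences the red over green sign was the same on all 4 arrays, and the lowest correlation of their ratios between arrays was 0.964. Their ratios followed the dye and not the diet, so they check the channels of the scanner files but not which RNA carried which dye. The exception had log2 ratios of -0.24, -0.55, 0.15 and -0.45. Of 537 negative control spots, between 20 and 31 were well above background per array.

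The pattern a reader would most want to follow up is that contigs with large differences in single replicates went in opposite directions between replicates, with no probe past the threshold. Noise of single spots as the cause is argued against by the 2 probes of a contig, whose lowest correlation on any array was 0.867, but noise from amplifying or labelling each RNA sample is shared by both probes and stays open. A wrong dye direction of replicate 1 or 3 as the whole cause needs a positive correlation of replicates 2 and 3 or of replicates 1 and 2, and these were at most -0.0593 over all tested probes, the brightest probes, median centring and all non-control probes. A wrong direction of replicate 2 and a probe-specific dye effect both need a positive correlation of replicates 1 and 3, so it cannot tell them apart. It was -0.19 over all tested probes, -0.12 with median centring and -0.16 with all non-control probes. These values argue against either as the whole cause over those probes. Among the 2802 brightest it was -0.11 (Spearman 0.0194, same sign for 53.6%). The bounds asked for values below 0 in every set, so there the test was undecided. As partial causes both stay open. A dye effect that differed between the 2 probes of a contig is argued against by their correlation, but one shared by both probes stays open. Differences between aphid pools unrelated to diet, and a response to nicotine that varied between pools, may also contribute and were not tested.

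The 3 replicates allow 4 ways of turning signs with mirror images counted once, too few for a share under 0.05. All 4 of 4 gave at least the real count of 47 probes with unadjusted p under 0.05, and the highest other was 981, from the choice that follows the dyes. The choices that turned replicate 1 or replicate 3 gave 676 and 736. Because all 3 pairs of replicates correlated negatively, turning any 1 of them makes 2 pairs positive, so these higher counts restate those correlations and add no evidence of their own. With a dye term in the model, which leaves 1 residual degree of freedom, the real count was 40.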

How the results depend on the processing

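Averaging the probes of a contig was chosen after seeing the data, and all other settings were preset. In all 14 alternatives 0 probes passed the threshold in limma, with a lowest adjusted p between 0.0888 (without replicate 3) and 1. The 4 named contigs kept their direction and stayed short of the threshold in all 14. With a dye term their mean log2 ratios were 1.32 for contig300, 1.87 for contig3790, -0.82 for contig2799 and -0.55 for contig3929. The count of probes with unadjusted p under 0.05, 47 as reported, was 89 with all non-control probes (14611 tested), 217 with the 4 arrays as independent samples, which overstates n, and 31 with the probes of a contig averaged (7687 tests). Leaving out 1 replicate gave between 148 and 190. It lay between 40 and 66 in the other settings. The correlations for replicates 1 and 2, 1 and 3, 2 and 3, and 2 and its repeat array were -0.34, -0.12, -0.43 and 0.972 with median centring only. With all non-control probes they were -0.0593, -0.16, -0.42 and 0.961, so each kept its sign. The cause of these shifts was not tested. The dye contrast was run only in the main setting, with median centring and without the repeat array, and gave 0 probes past the threshold in each. Its count under unadjusted 0.05 was 1259 with median centring and 994 without the repeat array. The correlation between repeat arrays, 0.981, was a moment estimate, because duplicateCorrelation gave none for 3 replicates on 4 arrays. The planned gene list alternatives were not run, because no list had members. Nicotine and control RNA of a replicate shared an array, so every fit was within pairs. Signal near background limits the control level of contig3790, and 3408 dim probes were not tested.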

Other observations

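The tests of dim probes, of a dye effect and of chance overlap were written down before their results were seen, and the account of probes under an unadjusted p of 0.05 was chosen after seeing the data. The 47 such probes belonged to 34 targets, 18 of which had 2 tested probes, and for 13 of these both probes lay under 0.05. In 12 of the 13 both probes were higher with nicotine. The median log2 ratio of the 45 higher probes was 1.32 in replicate 1, 1.11 in replicate 2 and 0.74 in replicate 3, and replicate 1 had the largest ratio for 27 of them. These probes were picked by their p-values, so their shared direction is a description and not a test.

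The contigs that differed at least 2-fold between the paired samples in every replicate, whatever the direction, were set against 2 technical explanations. Noise of dim probes as the cause of shared large differences is argued against among the 2802 brightest probes. Their rank correlation of absolute log2 ratios between replicates averaged 0.251, against a bound of 0.1 set in advance. How many of the 100 probes are among the brightest was not counted, so for dimmer members of the set this noise stays open. A single shuffle of values among probes of like intensity gave between 0.02 and 0.03 for the 3 pairs over all tested probes, where the real mean was 0.214. No shuffled value was computed for the brightest probes alone. A dye effect as the main cause is argued against because 36% of these probes had 1 red over green sign in all 3 replicates, below the 50% set in advance. The 95% exact binomial interval, 26.6 to 46.2%, treats probes as independent. Some contigs have 2 probes in the set, so this interval is too narrow. The 36 probes lie above the highest shuffled count of 16, but the whole set of 100 also lies above its highest shuffled count of 32. The shuffles had a mean of 5.84 such probes among a mean of 18.1, so the excess is not particular to a dye effect. A partial dye effect, noise from amplification or labelling and differences between pools in age, tissue carried along or handling could contribute to the pattern and were not tested.

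For the 6 probes of 4 contigs at least 2-fold higher with nicotine in all 3 replicates, chance overlap of independent replicates was tested by shuffling. The observed 6 lay within the shuffled range for probes higher in all 3, which had a mean of 1.80 and a highest count of 8. Counting either direction, the highest was 12, so the shuffled range does not exclude chance overlap. The share of shuffles that reached 6 was not counted. Shuffling moved single probes, although some of the 6 are 2 probes of 1 contig. The shuffles also held a mean of only 18.1 probes 2-fold apart in all 3 replicates, against 100 observed. Of those 100, 6% had 1 direction in all 3 replicates, where independent signs would give 25%. The 4 contigs include contig3790 and contig300. The other 2 lie outside the limit of 2 identifiers per direction, and their values were picked out after being seen. The 2 probes of the first had log2 ratios of 3.87, 2.66 and 1.13 and of 3.85, 2.57 and 1.14 in replicates 1, 2 and 3, with means of 2.55 and 2.52 (limma, adjusted p = 0.9998), or 1.89 and 1.85 without replicate 1. Both were well above background in both channels on 4 of 4 arrays. The probes of the second had 3.92, 1.05 and 1.20 and 3.45, 0.79 and 0.99, so its second probe was under 2-fold in replicates 2 and 3. Their means of 2.06 and 1.75 (limma, adjusted p = 0.9998) were 1.13 and 0.89 without replicate 1, and their control signal was well above background on 2 and 1 of 4 arrays, their nicotine signal on 3.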
